A study of Mus musculus with 8 samples.

How the data were processed

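The 8 samples were laser-captured tissue of female Apoe-/- mice after 3 months of a high-fat diet, 4 of early plaque and 4 of morphologically normal vessel wall. Per the labels, sections were deparaffinized, tissue was collected from at least 40 sections per mouse, total RNA was isolated with the RecoverAll kit, and the PCR probes carried the dye FAM. The instrument, reverse transcription, preamplification, threshold setting and software are not given in the sources used here. The authors deposited raw threshold cycles (Ct), neither normalised nor filtered as far as the values show, with a Ct of exactly 40 where an assay did not amplify. Of 4240 wells, 2249 held a 40 and 54 a Ct from 35 to under 40. The table has 530 rows, 341 from panel 1 and 189 from panel 2, told apart by the control RNAs that recur. They hold 517 mouse miRNA assays (335 and 182), 6 control RNAs and a plant control assay that read 40 in all wells. Assay names are those of an old miRNA catalogue, in which a star marks the less abundant strand. No genome build is named, so no positions are given. The title of plaque 4 calls it replicate 4 while its description says replicate 3, and the title was used.

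Depth on a PCR panel is the amount of RNA that entered the reactions. It was described by the number of miRNAs with a Ct under 35 and by the mean raw Ct of the 124 miRNAs detected in all 8 samples. A Ct of 35 or above counted as not detected, repeated wells of an assay were averaged over those that detected it, and each sample was centred by subtracting the mean Ct of those 124 miRNAs. The normalised level is the negative of the centred Ct. A difference of 1 cycle is a 2-fold difference if amplification is fully efficient, which was not measured. Levels of different assays are not comparable, since efficiencies differ.

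miRNAs detected in at least 3 of 4 samples of each group (172) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), on all 8 samples with group as the only term and values not detected left missing. P-values were adjusted by Benjamini-Hochberg over the 172, with 0.05 as the threshold. The labels call the samples biological replicates. Values per group are means ± SD over samples and errors of log2 fold changes are limma's SE. miRNAs detected in at least 3 samples of 1 group but in fewer of the other were compared by Fisher's exact test. Where the other group had 0, the fold is a lower bound, the detecting group's mean level against the mean of the other samples' level at a Ct of 35, and a fold is given only where all 4 samples of the detecting group detected the miRNA. Sample measures and control RNAs were compared by exact permutation of the group means over 70 arrangements, two-sided.

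There were 18 lists of cell type markers, miRNA families and genomic clusters, fixed before the data were examined, of which 16 had at least 3 tested members. They were tested by limma's cameraPR with a preset correlation of 0.01, adjusted over the 16. Beside it, camera with a correlation estimated from the residuals and fry were run on the miRNAs detected in all samples, where 14 lists had at least 3 members. Lists share members: miR-1, miR-133a and miR-133b stand on the smooth muscle and heart lists, miR-28 on the smooth muscle and lymphocyte lists, and most miRNAs listed for a cell type are also made elsewhere.

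The rule for named miRNAs was fixed beforehand: the 12 called miRNAs with the largest fold in each direction, the 2 members of each tested list with the largest fold, 20 miRNAs chosen for their known roles in arteries and leukocytes, the control RNAs, and those detected in 4 of 4 samples of a group and 0 of 4 of the other. miR-100, miR-125b-5p, miR-28, let-7i, miR-30e and miR-103, which complete an account of a list, and miR-208, let-7a, miR-382 and miR-124 were added after their values were seen.

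The miRNAs and groups named under other observations were also chosen after their values were seen. The steps were tested on simulated tables made with the assay means, sample offsets and residual spread of this comparison of plaque with undiseased artery, over 20 tables of on average 264 tested assays. limma called 8.76% of simulated log2 changes of 1, 52.4% of changes of 2, 86.4% of changes of 3 and 98.6% of changes of 5, with 6.28% of calls false. Tables with no change gave 0.05 calls on average. A 2-fold difference thus mostly went uncalled in the simulation. Unlike the data, its noise was independent between assays, equally wide in both groups and without a shift between panels. The shares called and the share of false calls may therefore not carry over to these samples.

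Alternatives fixed beforehand were a detection cutoff of 32 or 38, the median, the control RNAs, U6, quantile normalization or raw Ct in place of the mean, values not detected set to the cutoff, only miRNAs detected in all samples, no filter, an exact permutation test per miRNA, array weights, a 2-fold minimum, omission of each sample and the replicate number as a block. Where a sample was omitted, a miRNA undetected in 1 of the remaining samples of its group was still tested, on the others. Alternatives added after seeing the data were centring of each panel, omission of plaque 2 and 3 together, undiseased artery 4 alone against plaque, mean raw Ct as a covariate, and omission of Ct values within 0.05 of a whole number. Such values made up 17.4, 16.3, 22.1 and 16.0% of wells under 35 in undiseased artery 1 to 4 and 17.3, 25.3, 39.6 and 13.9% in plaque 1 to 4, where 10% would be expected by chance. The reason is not given in the sources used here. Figures were drawn with matplotlib 3.10.9.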

Results

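The study measured miRNAs by real-time PCR in female Apoe-/- mice, which lack apolipoprotein E and develop atherosclerosis on a fat-rich diet. After 3 months on that diet, plaque and vessel wall of normal appearance were cut from arterial sections by laser capture microdissection. Each group had 4 biological replicates, called plaque 1 to 4 and undiseased artery 1 to 4. The table held raw threshold cycles (Ct, the cycle at which fluorescence crossed a set line, so that a higher Ct means less RNA) for 517 mouse miRNA assays on 2 panels. Per the labels, plaque came from the aortic root and undiseased tissue from an artery, so vessel site and plaque cannot be told apart. The labels do not say whether both tissues came from the same mice, and the study's 10-month diet arm was not analysed here.

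Plaque samples gave fewer miRNAs and later amplification than undiseased artery, by differences that did not pass an exact test. At a Ct under 35, 288, 265, 274 and 227 miRNAs were detected in undiseased artery 1 to 4, and 232, 175, 148 and 240 in plaque 1 to 4. The means were 264 ± 26.1 and 199 ± 44.5 (SD, n = 4 each), a difference of -64.8 (exact permutation test, two-sided, p = 0.0857). The mean raw Ct of the 124 miRNAs detected in every sample was 25.3 ± 0.885 in undiseased artery and 28.0 ± 1.65 in plaque. This difference of 2.70 cycles had an exact p of 0.0571, and 0.0286 is the smallest p that 70 arrangements allow. Without plaque 4 it was 3.29 cycles (exact p = 0.0286, 3 against 4 samples), the smallest p that design allows. All fold changes below are relative to this mean, which was subtracted from each sample.

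**Figure D1:**
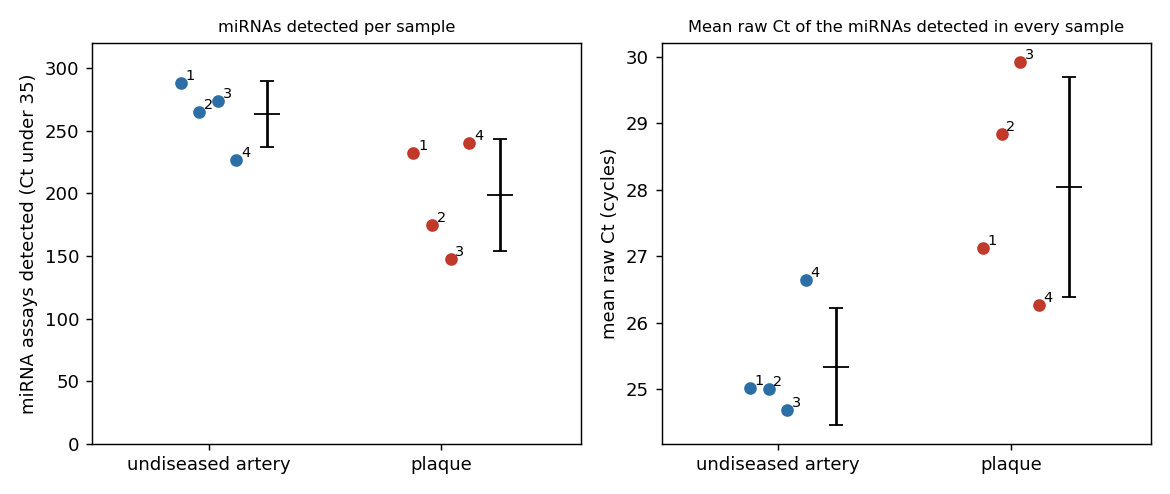
Number of miRNA assays detected (left) and mean raw Ct in cycles of the miRNAs detected in every sample (right), with points for samples numbered by replicate and a bar for the mean and SD of 4. Plaque 2 and 3 had the fewest miRNAs, 175 and 148, and undiseased artery 4 had 227 against 265 to 288 in the other undiseased samples.

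The first question was which miRNAs differed between early plaque and undiseased wall. The largest differences among the 172 miRNAs tested were falls of the smooth muscle miRNAs miR-145 and miR-143, which are transcribed from a shared cluster and accompany the contractile state. miR-145 was 39.5-fold lower in plaque (log2 fold change -5.30, SE 0.476, adjusted p = 3.51e-05) and miR-143 was 30.8-fold lower (-4.95, SE 0.521, adjusted p = 9.03e-05), with all 4 plaque samples below all 4 undiseased ones. Among the miRNAs that rose were miR-155, which activated macrophages and lymphocytes induce, by 6.91-fold (2.79, SE 0.635, adjusted p = 0.0117) and miR-146b, a paralogue of the NF-κB-induced miR-146a, by 12.1-fold (3.60, SE 0.652, adjusted p = 0.00382). Members of the let-7 and miR-30 families fell.

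Of 172 miRNAs detected in at least 3 of 4 samples of each group, 59 passed an adjusted p of 0.05 in limma (Benjamini-Hochberg), 27 higher and 32 lower in plaque. Their fold sizes ran from 2.30 to 39.5. In 45 of the 59, plaque and undiseased samples did not overlap. Over all tested miRNAs this held for 32.6%, against 2.86% expected by chance for 4 against 4. The calls depended on the reference. With the mean of the control RNAs, or with U6 alone, 0 rose and 2 fell (miR-143 and miR-145). On raw Ct 0 rose and 81 fell. All 59 kept their direction with control RNAs and with U6, where the calls were lost and not the signs, and 47 kept it on raw Ct. The median log2 fold change of all tested miRNAs was -0.11 with the main reference, -0.45 with control RNAs, -0.44 with U6 and -2.59 on raw Ct. A per-assay exact permutation test, whose smallest p is 0.0286 with 4 values a group, gave 51 miRNAs with an unadjusted p under 0.05 and 0 after adjustment, the lowest adjusted p being 0.0964. A minimum fold of 2 in the test left 8 calls.

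Single samples mattered. Without undiseased artery 1, 2 or 3 there were 25, 19 and 20 calls, and without the 5 other samples, each in turn, 45 to 67. With mean raw Ct as a covariate, chosen after seeing the data, 7 miRNAs rose and 6 fell. The assay panel also went with the direction: of the miRNAs that rose, 7 were on panel 1 and 20 on panel 2, and of those that fell, 30 were on panel 1 and 2 on panel 2. The median log2 fold change was -0.73 on panel 1 (109 tested) and 0.82 on panel 2 (63 tested). With each panel centred on its own mean, also chosen later, 15 rose and 20 fell. There were 25 miRNAs called under centring on the mean, on the median, on each panel and under quantile normalization, 12 higher and 13 lower.

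**Figure D2:**
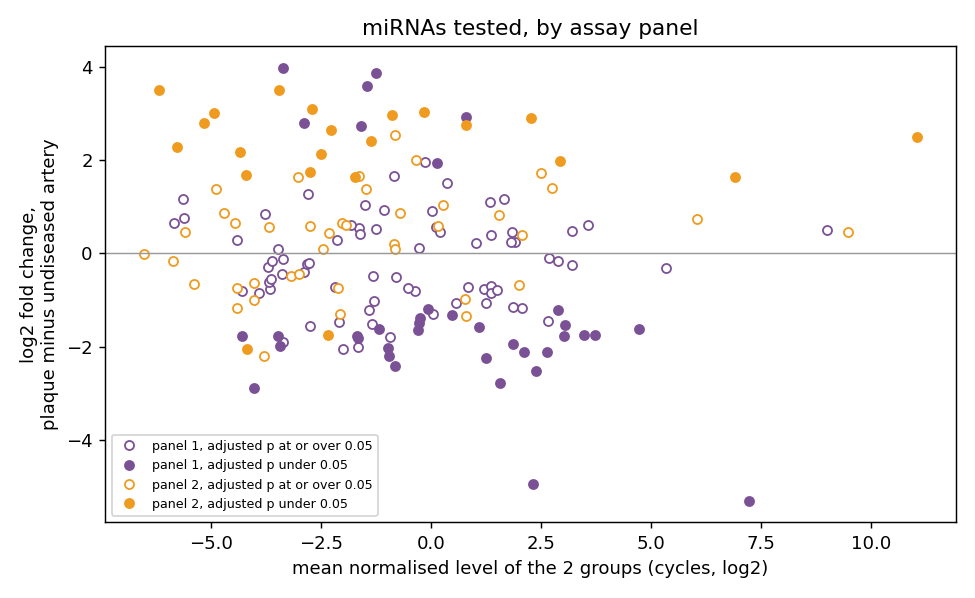
Log2 fold change (plaque minus undiseased artery) of the 172 tested miRNAs against their normalised level in cycles, the mean of both groups, coloured by panel and filled where the adjusted p was under 0.05. Filled points above 0 were mostly on panel 2 (20 of 27) and those below 0 mostly on panel 1 (30 of 32).

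Most tested vascular smooth muscle miRNAs fell, though the test of the list depended on the correlation assumed between its members. Of the 10 tested members of a list fixed before the data were examined, 7 fell, 0 rose and 3 did not pass, with a median log2 fold change of -1.88. Adjusted over the list alone, the same number, 7, fell. Besides miR-143 and miR-145, miR-204 (-2.24, SE 0.655, adjusted p = 0.0307, 3 plaque samples), miR-99a (-2.12, SE 0.469, adjusted p = 0.0101), miR-100 (-1.94) and miR-125b-5p (-1.63) fell. The other faller, miR-28 (-1.82), stands on the lymphocyte list too. The 3 members that did not pass, miR-1 (0.61), miR-133a (-0.26) and miR-133b (1.10), are the ones shared with striated and heart muscle. The list passed camera with a preset correlation of 0.01 (adjusted p = 0.00126), the only 1 of 16 tested lists to do so, and fry (adjusted p = 3.22e-04). The call was lost with an estimated correlation of 0.341 (adjusted p = 0.677, unadjusted p = 0.0669). All 7 fallers were on panel 1. The list was called lower under all references tried with the preset correlation, whereas miR-204, miR-100 and miR-125b-5p were not called with quantile normalization or panel centring, nor miR-28 with panel centring, and with control RNAs or U6 miR-143 and miR-145 alone were called. miR-143, miR-145 and miR-99a were called in each of the 8 fits that left out 1 sample. Without undiseased artery 1, 2 or 3, miR-204 (-2.66 to -1.47 over the 8 fits, nearest 0 without plaque 1), miR-100 (-2.31 to -1.58), miR-125b-5p and miR-28 were not called, nor was miR-204 without plaque 1, miR-125b-5p without plaque 3 or miR-28 without plaque 2.

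Some miRNAs of leukocytes rose. Of 9 tested members of the leukocyte and myeloid list, 4 rose, 0 fell and 5 did not pass, and adjusted over the list alone 4 rose. Next to miR-146b and miR-155, miR-342-3p (2.92, SE 0.997, adjusted p = 0.0428) and miR-21 (1.93, SE 0.585, adjusted p = 0.0323), a miRNA raised in many inflamed tissues, were higher. miR-146a (1.50, adjusted p = 0.132), miR-142-3p (-0.22, adjusted p = 0.878) and miR-150 of mature lymphocytes (-0.85, adjusted p = 0.425) did not pass. miR-223, a neutrophil and monocyte miRNA, also did not pass (0.50, adjusted p = 0.903), but this value cannot be read as a comparison. Its raw Ct was 22.4, 10.7, 10.6 and 22.7 in undiseased artery 1 to 4 and 23.3, 10.3 and 20.8 in plaque 1, 2 and 4, with no detection in plaque 3. These values stayed in the counts, in the list's median and in camera with the preset correlation. The 4 risers were on panel 1. The list did not pass camera (median 1.50, adjusted p = 0.170, and 0.677 with an estimated correlation), and its median was -1.20 on raw Ct. fry, which asks whether the members moved on balance in 1 direction without comparing them with other miRNAs, gave an adjusted p of 0.0346, and 7 of the 14 lists it was run on passed. The leukocyte and myeloid list passed camera with each panel centred, with mean raw Ct as a covariate, without plaque 2 and 3 together and with replicate number as a block.

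The calls of miR-342-3p and miR-21 rested on few samples. miR-342-3p spread widely in plaque, with levels of 2.78, -0.14, 0.95 and 5.49 in plaque 1 to 4, and among the leave-out fits it kept its call only without plaque 2 (3.73) or without plaque 3, and without plaque 4 its rise was 1.85. Of the 6 other references, panel centring alone kept it. miR-21 kept it only without plaque 4, where the rise was 2.49, and on raw Ct its difference was -0.77. The call of miR-155 held in all 8 such fits (2.29 to 3.16), as did that of miR-146b (2.95 to 4.11, the lowest without plaque 4). Neither was called with control RNAs or U6, nor on raw Ct, where the differences were 0.09 for miR-155 and 0.90 for miR-146b. miR-146a passed without plaque 3 (2.18). miR-342-5p, the other arm of the miR-342 hairpin, was detected in plaque 1 (Ct 34.0) and plaque 4 (Ct 31.0) and in 0 of 4 undiseased samples (Fisher's exact test, p = 0.429). miR-142-5p was detected in 4 of 4 undiseased and 1 of 4 plaque samples (exact p = 0.143).

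**Figure D3:**
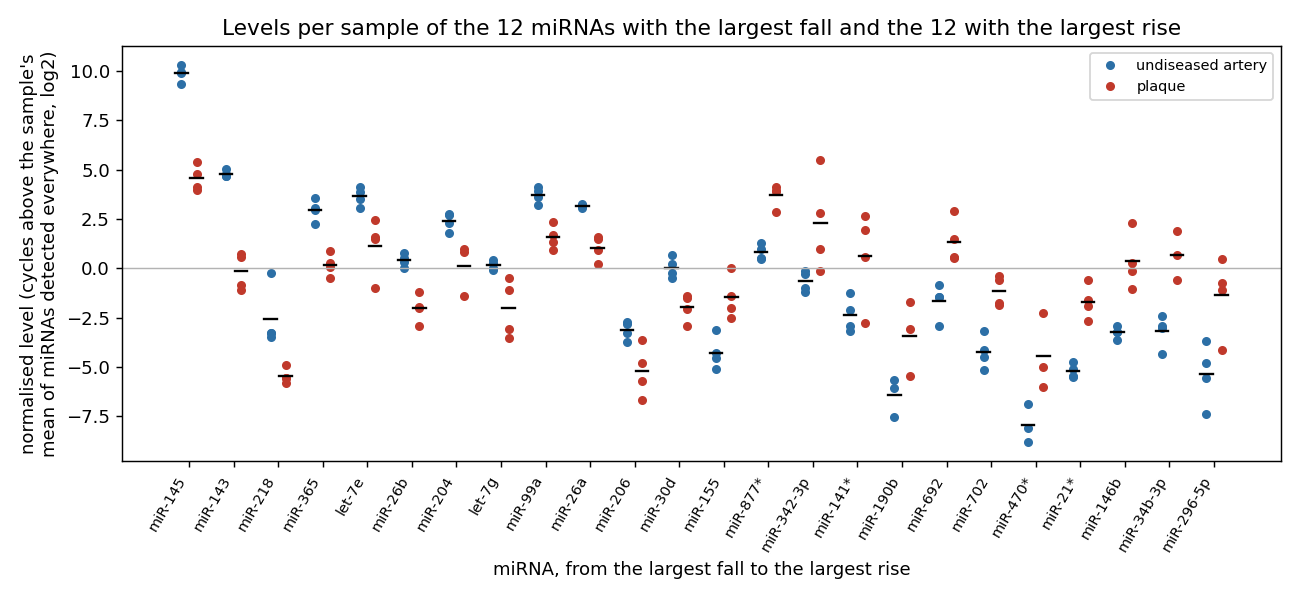
Normalised level per sample, in cycles above the sample's mean on a log2 scale, of the 12 called miRNAs with the largest falls (left) and the 12 with the largest rises (right); points are samples and bars group means. miR-145 lay between 9.34 and 10.3 in undiseased artery and between 3.98 and 5.39 in plaque.

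The let-7 and miR-30 families, both abundant in differentiated tissue, fell in most members. Of 6 tested let-7 miRNAs 5 fell, led by let-7e (-2.53, SE 0.688, adjusted p = 0.0223) and let-7g (-2.19, SE 0.673, adjusted p = 0.0327), and let-7i (-0.77) did not pass. Of 5 miR-30 miRNAs 4 fell, led by miR-30d (-2.02, SE 0.500, adjusted p = 0.0153) and miR-30c (-1.77, SE 0.406, adjusted p = 0.0117), and miR-30e (-0.73, passing without plaque 4) did not pass. The same counts fell when adjusted over each list alone. Their medians were -1.75 and -1.33, below 0 under all references. All tested members were on panel 1, where the median over all 109 tested miRNAs was -0.73. Only let-7e, miR-30c and miR-30d were called under the median, quantile and panel references alike, and no member was called with control RNAs or U6. As lists, neither passed camera (adjusted p = 0.0816 for both, and 0.677 for both with an estimated correlation), whereas fry gave adjusted p values of 0.0227 for let-7 and 0.00183 for miR-30. The let-7 list passed without plaque 1, with control RNAs, with U6 and with replicate number as a block. let-7e was not called without undiseased artery 1, 2 or 3 (-2.97 to -1.77 over the 8 fits, nearest 0 without plaque 3), and miR-30c and miR-30d were not called without undiseased artery 2 or 3. Among the leave-out fits let-7g kept its call only without plaque 1 or without plaque 4 (-2.71 to -1.69), and quantile normalization and panel centring ended it.

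Of 4 tested miR-15/16 miRNAs, the linked pair miR-497 (-1.78, adjusted p = 0.0146) and miR-195 (-1.20, adjusted p = 0.0407) fell and 2 did not pass. This list's median was -0.95 (camera adjusted p = 0.338, fry adjusted p = 0.0227). In the miR-17 family clusters, 1 of 7 tested members, miR-25 (-1.78, adjusted p = 0.0463), fell, and miR-93 (-1.52, adjusted p = 0.0661, passing without plaque 1) did not pass (median -1.07, camera adjusted p = 0.338, fry adjusted p = 0.0485). In the miR-23/24/27 clusters miR-23b fell (-1.39, adjusted p = 0.0461) and 3 did not pass, among them miR-27b (-0.74, adjusted p = 0.443), with a median of -0.53 (camera adjusted p = 0.821). Of 8 tested miRNAs from the imprinted Dlk1-Dio3 cluster, miR-127 fell (-1.49, adjusted p = 0.0474) and 7 did not pass, such as miR-667 (1.66, adjusted p = 0.0540, passing without undiseased artery 1). That list's median was 0.01 (camera adjusted p = 0.954) and below 0 with the median, control RNA, U6, quantile and raw Ct references. Adjusted over each list alone, 0 members of the miR-17, miR-23/24/27 and Dlk1-Dio3 lists passed. The calls of miR-195, miR-25, miR-23b and miR-127 were each lost in 6 or 7 of the 8 fits that left out 1 sample, undiseased artery 1, 2 and 3 being among them each time. Panel centring ended all 4 calls, and the median and quantile references ended those of miR-25 and miR-127. miR-497 lost its call without undiseased artery 2 or 3.

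Few markers of endothelium or blood passed. Of 7 tested endothelial miRNAs, miR-218, which lies in introns of the Slit genes, fell (-2.89, SE 0.705, adjusted p = 0.0146) and 6 did not pass. Among these were both arms of the endothelial miR-126, miR-126-3p (-1.15, adjusted p = 0.291) and miR-126-5p (-2.02, adjusted p = 0.0655, which passed without plaque 1), as well as miR-221 (0.22, adjusted p = 0.805) and miR-222 (1.17, adjusted p = 0.235, which passed without plaque 3). The endothelial median was -1.15 (-1.83 to -0.33 with 1 sample left out, camera adjusted p = 0.821). Over all 27 alternatives it reached 0.21, so its sign was not kept throughout. Undiseased artery 1 held the level of miR-218 up at -0.24, against -3.50 to -3.29 in the other undiseased samples, and without it the fall was -2.12, still called. Of 5 tested blood cell miRNAs, miR-25 fell, and the erythroid miR-451 (-1.56, adjusted p = 0.0878) was among 4 that did not pass (median -1.07, camera adjusted p = 0.431, fry adjusted p = 0.0227). Adjusted over the list alone, 0 blood cell miRNAs fell.

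Fibroblast and matrix miRNAs moved both ways. Of 8 tested, miR-21 rose, miR-30c fell and 6 did not pass (median -0.18, camera adjusted p = 0.867), with a sign that turned under quantile normalization and panel centring. Of 6 lymphocyte miRNAs, miR-155 and miR-342-3p rose, miR-181a (-1.65, adjusted p = 0.0428) and miR-28 fell and 2 did not pass (median 0.33, camera adjusted p = 0.867). The sign of the lymphocyte median turned with control RNAs, U6 and raw Ct, and miR-181a kept its call only without plaque 2 among the leave-out fits and lost it with quantile normalization and panel centring. Of the 3 tested heart muscle miRNAs, all also on the smooth muscle list, 0 passed (median 0.61, camera adjusted p = 0.821). miR-133b (1.10, adjusted p = 0.0947) was called higher with quantile normalization and with panel centring. The level of miR-133a was -2.13 in plaque 2, and 4.33, 4.15 and 5.97 in plaque 1, 3 and 4. In undiseased artery it was 2.82 to 3.94. miR-208, which is encoded in heart myosin genes, was detected in plaque 1 (Ct 31.4) and plaque 3 (Ct 34.0) and in 0 undiseased samples. miR-1, undetected in plaque 2, passed without plaque 4 (1.54), a fit that held plaque 1 and 3 alone.

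In the perivascular fat list miR-365 fell (-2.79, SE 0.480, adjusted p = 0.00369) and 4 of 5 did not pass, among them miR-455 (1.96, adjusted p = 0.0866, passing without plaque 4) and miR-378 (0.86, adjusted p = 0.434). Its median was 0.66, its mean -0.15 and its test pointed lower (camera adjusted p = 0.867). Of 4 liver and lipid miRNAs, miR-192 (0.85, adjusted p = 0.240) included, 0 passed (median 0.18, camera adjusted p = 0.867). In the hypoxia and stress list miR-34b-3p, of a family that p53 induces, rose (3.86, SE 0.693, adjusted p = 0.00422, 4 undiseased and 3 plaque samples, called in all 8 leave-out fits, with 4.48 without plaque 1 and 3.25 without plaque 4), miR-181a fell and miR-103 (-1.22, adjusted p = 0.170, passing without plaque 1) did not pass. That list's median was -1.22, while its mean of 0.33 and its test pointed higher (camera adjusted p = 0.867). The median was -1.61 to 1.69 with 1 sample left out, above 0 without plaque 2, 3 or 4. Plaque 3 did not detect miR-34b-3p or miR-103, so their fits without plaque 1 held plaque 2 and 4 alone. The fit of miR-34b-3p without plaque 4 held plaque 1 and 2 alone. On raw Ct the medians of the heart muscle, fat and liver lists were also below 0, and that of the liver list turned with control RNAs, U6 and panel centring too, as that of the fat list did with panel centring and that of the miR-23/24/27 clusters with the last alone. Leaving out 1 sample also turned the sign of the lymphocyte median (without plaque 2, 3 or 4), the liver median (without plaque 1, 2 or 3), the heart muscle median (without plaque 3), the fibroblast median (without undiseased artery 2) and the Dlk1-Dio3 median (without undiseased artery 2, 3 or 4 or plaque 1 or 4). Neuron and epithelium lists had 2 and 1 tested members and were not tested.

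**Figure D4:**
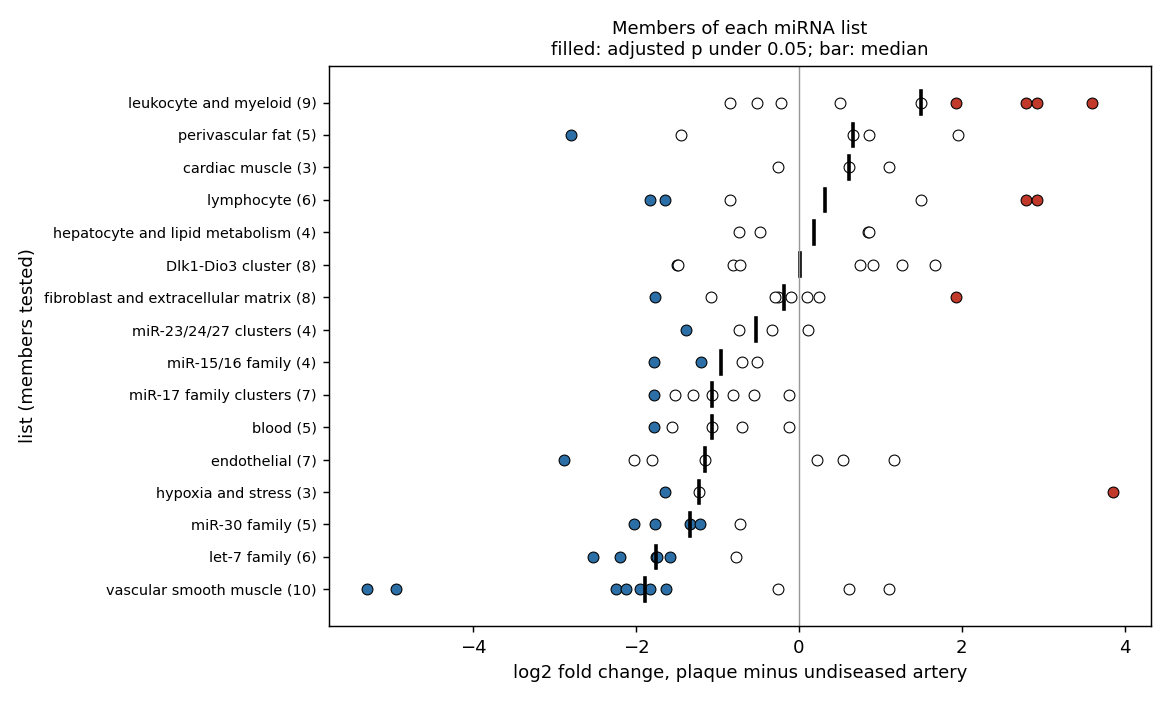
Log2 fold change (plaque minus undiseased artery) of the tested members of 16 lists, filled where the adjusted p was under 0.05, with a bar at each list's median; the number tested is in parentheses. In the vascular smooth muscle row, 7 of 10 members are filled and below 0, and in the leukocyte and myeloid row, 4 of 9 are filled and above 0.

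Outside the lists, the largest rises were those of miR-296-5p (3.98, SE 0.993, adjusted p = 0.0153), miR-21* (3.50, SE 0.515, adjusted p = 0.00152), the strand opposite miR-21, and miR-470* (3.49, SE 0.965, adjusted p = 0.0271, 3 samples per group). miR-702 (3.08), miR-692 (3.03), miR-190b (3.00), miR-141* (2.96) and miR-877* (2.90) followed. Of these 8, all but miR-296-5p were on panel 2. miR-296-5p, miR-21*, miR-702, miR-692 and miR-877* were called in all 8 fits that left out 1 sample, though miR-296-5p moved to 3.30 without undiseased artery 4, 3.37 without plaque 2 and 4.90 without plaque 4. miR-470* was not called without undiseased artery 2 or 3. miR-190b kept its call only without plaque 2 or plaque 4, and miR-141* only without plaque 4. Without plaque 3 the rises of miR-470*, miR-190b and miR-141* were 2.49, 2.24 and 2.33, and without plaque 4 they were 4.29, 4.03 and 4.09. Quantile normalization and panel centring ended the calls of miR-470*, miR-190b and miR-141* and kept those of the other 5. With the mean raw Ct as a covariate miR-141* turned to -0.37. The remaining large falls were those of miR-26b (-2.43, SE 0.479, adjusted p = 0.00584) and miR-26a (-2.11, SE 0.450, adjusted p = 0.00881), both called in all 8 such fits, and of the muscle miRNA miR-206 (-2.05, SE 0.634, adjusted p = 0.0331). miR-206 was not called without plaque 1 or without any 1 undiseased sample.

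Some miRNAs were measurable in undiseased artery alone. There were 12 detected in 3 or 4 of 4 undiseased and 0 of 4 plaque samples, and 0 the other way round. miR-129-3p was the only 1 found in 4 of 4 against 0 of 4 (Fisher's exact test, p = 0.0286, the smallest this design allows). By the group means it was at least 11.5-fold lower in plaque (at least 4.66-fold to 22.3-fold with 1 undiseased sample left out, the least without undiseased artery 1). This bound holds for the means alone, since its levels in undiseased artery 1 to 4 were 0.48, -2.66, -5.26 and -6.30. Loss through less RNA cannot be told apart from a fall for it, as weighed below. Of the 11 found in 3 of 4 (exact p = 0.143 each), let-7a had a raw Ct of 22.1 ± 0.149 (SD) in undiseased artery 1 to 3. It was also undetected in undiseased artery 4, as were miR-382 and neuronal miR-124, singled out after their values were seen, so no fold is given for these 3. A further 66 miRNAs were detected in 3 or 4 undiseased and 1 or 2 plaque samples, among them miR-322 (3 of 4 and 1 of 4), and 2 the other way round.

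Of the 80 miRNAs compared by detection, Fisher's exact test gave 0 with an adjusted p under 0.05 (lowest 0.394) and 1 with an unadjusted p under 0.05. With 4 samples a group its smallest p is 0.0286, so a single miRNA could not pass after adjustment, whatever its detection. The number found in 1 group was 24 at a Ct under 32, and it rose to 19 without undiseased artery 2, 25 without undiseased artery 4, 23 without plaque 1 and 27 without plaque 4, where fewer samples had to agree.

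The 6 control RNAs, small nuclear and nucleolar RNAs and the Y1 RNA, did not differ past the threshold. After subtraction of the mean of the miRNAs, the differences between plaque and undiseased artery were 0.45 for U6 (10.1 ± 2.11 in plaque and 9.66 ± 0.590 in undiseased artery, SD, n = 4 each, exact p = 0.714), -0.81 for U87, 1.75 for Y1 (exact p = 0.0571), 0.36 for snoRNA135, 0.27 for snoRNA202 and 0.88 for snoRNA429. The lowest of the 6 adjusted p values was 0.343. On raw Ct, U87 came 3.51 cycles later in plaque (exact p = 0.0286, adjusted p = 0.171). Its exact p is the smallest that this test allows, so a control that alone separated the groups could not pass. That none passed therefore does not show that the controls were stable. The mean raw Ct of the 6 was 20.5 ± 0.654 in undiseased artery and 22.7 ± 1.74 in plaque, a difference of 2.21 cycles (exact p = 0.0857). The difference of U6 was -0.23 without plaque 4, that of U87 0.13 without plaque 1, that of snoRNA135 -0.05 without plaque 2 and that of snoRNA202 -0.15 without undiseased artery 1. On raw Ct all but U87 had the opposite sign.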

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

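The tests of the panel reactions, the intervals of what is left of the panel gap, the calls by panel with the covariate, and the tests of RNA amount and reference for miR-143 and miR-145, of other smooth muscle miRNAs and of a run difference in detection were chosen after the results they bear on had been seen.

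Of 117 groups of 4 samples examined for 1 sample standing apart (by its gap to the nearest sample as a share of the whole range), 7 had such a sample, 5.98% where chance gives about 5%. The mean raw Ct of undiseased artery 4 was 26.65, against 24.69 to 25.02 in the other undiseased samples. Plaque 1 stood low for the control RNAs U87 (-1.05, others 2.43 to 3.09) and snoRNA202 (5.52, others 7.97 to 8.04). The level of miR-218 was -0.24 in undiseased artery 1 (others -3.50 to -3.29) and that of miR-21 was -0.54 in undiseased artery 3 (others -0.94 to -0.88). miR-25 was at -5.93 in plaque 2 (others -4.04 to -3.69) and miR-27b at -3.27 in plaque 4 (others -0.35 to 0.08).

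The fall of miR-143 and miR-145 was weighed first. The tables argue against a smaller amount of RNA as its whole cause: with mean raw Ct as a covariate the changes were -4.76 (adjusted p = 0.00495) and -5.10 (adjusted p = 0.00218), and over their other alternatives adjusted p ran up to 0.0964. They argue against the choice of reference, since over 7 references the change nearest to 0 was -4.39, with adjusted p up to 0.0049. A run that set undiseased artery 1 to 3 apart is also opposed, since undiseased artery 4 exceeded the highest plaque sample by 3.95 cycles for both (3.945 for miR-143). What stays open is whether plaque held fewer smooth muscle cells or lower levels in each, since the other 8 tested members of the list had a median of -1.72 (-2.24 to 1.10, 5 called lower) but are made by other cells too, and vessel site, which the design confounds with plaque.

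The split of directions by panel was weighed next. Once the spread of the panel gap is counted, no value in the tables excludes either technical cause tested. Reactions may have run differently on the panels: the 5 control RNAs assayed on both shifted towards panel 2 in plaque by 0.552 (95% interval -0.02 to 1.12, exact p = 0.0286). The whole interval is below the gap of 1.54 between the panels' median log2 fold changes. This met the criterion written down for opposing that cause, but the criterion left out the spread of the gap. After subtraction of each sample's control shift the per-sample gap still differed by 1.08, with a 95% interval of -0.11 to 2.27, which includes 0. A smaller amount of RNA in plaque is the other candidate explanation. Within groups, samples with a higher mean raw Ct had higher panel 2 levels relative to panel 1, by 0.39 per cycle (SE 0.064, exact permutation within groups, p = 0.0139). This predicts 1.052 (SE 0.173) of the 1.63 by which the per-sample gap differed between groups. The shortfall of 0.58 exceeded 2 SE of the prediction, the bound set beforehand, but that bound left out the spread of the gap itself, and the 95% interval of the shortfall, -0.0047 to 1.16, includes 0. With mean raw Ct as a covariate the calls no longer split by panel (4 higher and 4 lower on panel 1, 3 higher and 2 lower on panel 2), while the panels' medians stayed apart at -0.55 and 0.23. With 4 samples a group, what stays open is each cause and both together. A difference in the miRNAs that the panels hold stays open too.

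The 12 miRNAs found in undiseased artery alone were weighed last. For 3 of them (let-7a, miR-382 and miR-124) less RNA is opposed, since the Ct expected in plaque from the level in undiseased artery 1 to 3, which alone detected them, was at most 32.4 in any plaque sample, over 2 residual SDs (0.959 cycles each) under 35. For the other 9, loss through less RNA cannot be told apart from a fall. Of these, 7 had an expected Ct of 35 or more in at least 1 plaque sample. The highest expected Ct was 33.79 for miR-199a-5p and 33.36 for miR-129-3p, under 35 by less than 2 residual SDs. The lowest for miR-129-3p was 29.7, but this rests on the mean of undiseased levels that ran from -6.30 to 0.48. Whether a run set undiseased artery 1 to 3 apart from the other 5 samples stays open. Of 8 abundant miRNAs absent from undiseased artery 4, 37.5% were absent from all plaque samples, but these are the same 3 that raised the question, so the share does not test it. A difference between plaque and wall stays open for all 12, none of which passed Fisher's exact test on detection after adjustment (adjusted p = 0.394).

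Other ways of splitting the 8 samples into 4 and 4 gave fewer calls. Of 35 splits, 1, the real one, gave 59 and the highest of the others gave 4. This sets the real split apart without excluding chance. The smallest share possible is 1 of 35, and the other splits mix plaque with undiseased samples. The count of lists did not set the real split apart. At least the 1 list called was reached in 12 of the 35 splits, and the highest count in another split was 3. The smooth muscle list had its smallest p, 7.87e-05, in the real split (0.00548 in the next).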

How the results depend on the processing

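Centring of each panel, omission of plaque 2 and 3 together, undiseased artery 4 alone, mean raw Ct as a covariate and omission of near-whole Ct values were chosen after seeing the data; the other settings were planned.

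The count of 59 called miRNAs moved by over 1.5 times under 11 of 27 alternatives. It was 2 with control RNAs, 2 with U6, 0 with the exact permutation test (51 with an unadjusted p under 0.05, lowest adjusted p 0.0964), 8 with a 2-fold minimum, 35 with panel centring, 13 with the covariate, 26 without near-whole values (111 tested) and 0 with undiseased artery 4 alone (9 with an unadjusted p under 0.05, 1 sample assumed to vary like the others). Omitting 1 sample gave 19 to 67. It was 81 on raw Ct, and 38 of the 59 were kept under quantile normalization. The cause was not tested unless named. miR-143 and miR-145 were called under all settings but the permutation test and undiseased artery 4 alone.

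The 1 called list, smooth muscle, was called under all 27 alternatives with the preset correlation (the exact test per miRNA leaves the list test as it was) and was lost with an estimated one (0 lists). 2 lists passed with control RNAs, U6, panel centring, the covariate and without plaque 2 and 3, and 1 to 2 when 1 sample was omitted. Whether replicate numbers pair the samples stays unknown, since weak correlations cannot exclude it. Correlations of same-numbered deviations were 0.130, 0.191, -0.245 and -0.155. Undiseased artery 1 and 2 and plaque 2 matched their own number best, and the other samples did not. With the replicate block 49 miRNAs (27 higher, 22 lower, 44 of the 59) and 3 lists passed, and the detected number still differed by -64.75 (exact sign flips, p = 0.25).

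miRNAs found in 1 group were 24 at a Ct under 32 and 14 to 27 when a sample was omitted. The detected number differed by -78.5 to -47.8 and mean raw Ct by 2.12 to 3.29 cycles with a sample omitted. For control RNAs 0 passed under all 10 alternatives, in a test that a control separating the groups alone could not pass. miR-21 turned to -0.77 on raw Ct, miR-141* to -0.37 with the covariate, and miR-133a to 1.91 (adjusted p = 0.0443) without plaque 2 and 3. For single miRNAs, controls and lists, 1451 values kept direction and side of the threshold, 379 lost the call, 38 gained one and 87 uncalled values changed sign. Low detection in plaque 2 and 3 limits what can be tested. Without them 203 and 205 miRNAs could be tested, against 178 and 176 without plaque 1 and 4. In all 4 fits fewer plaque samples had to detect a miRNA than in the main fit with its 172.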

Other observations

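All groups and single miRNAs here were chosen after their values were seen, and the changes were checked under 6 other references and without each sample.

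Of 8 tested miRNAs named miR-99, miR-100 or miR-125, which share clusters with let-7 genes, 4 fell, 0 rose and 4 did not pass. Their median of -1.16 stayed below 0 under the 6 references, though 0 passed with control RNAs or U6 1 with quantile normalization or panel centring, 1 without undiseased artery 1, 2 or 3 and 2 without plaque 3.

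The 3 tested miRNAs with miR-466 or miR-467 names, all on panel 2, rose with the mean as reference, miR-466d-3p (1.64), miR-467a* (1.98) and miR-467b* (2.12). Their calls depended on the reference: 0 passed with control RNAs, U6 or panel centring, though the median stayed above 0 with each of these. On raw Ct the median was -0.72, and 0 passed without undiseased artery 1, 2 or 3. miR-34c* (1.74, adjusted p = 0.0407), of the family of miR-34b-3p, rose too, but it was called under none of the 6 other references (-0.96 on raw Ct) and, among the 8 fits that left out 1 sample, only without plaque 1.

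Of 36 tested star strands, 11 rose and 1, let-7a* (-1.76), fell. The catalogue names these as the less abundant partners of a hairpin, which was not tested in these tissues. All were on panel 2, where 9 of 27 other strands rose and 1 fell, with a median log2 fold change of 1.39 against 0.51 for the star strands. With panel centring the median of the star strands turned to -0.51 (2 rose, 7 fell), and on raw Ct to -1.97, and 0 passed as higher with control RNAs or U6. The count of rises rested on single samples too: it was 3, 2 and 3 without undiseased artery 1, 2 and 3 and 6 without undiseased artery 4, plaque 2 or plaque 3, and without plaque 4 the median was 0.06. For the other strands it was 5 without undiseased artery 1, 2 or 3, 6 without plaque 3 and 14 without plaque 4, 4 with panel centring and 0 with control RNAs, U6 or raw Ct.

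The earliest amplifying miRNA assay that rose was miR-720, now known to match a tRNA fragment, by 2.49 (SE 0.438, adjusted p = 0.00369). It was called without each sample in turn and with the median, quantile and panel references, not with control RNAs or U6, and on raw Ct its difference was -0.20. Replicates correlated across the 124 miRNAs detected everywhere at r = 0.945 to 0.988 in undiseased artery and 0.779 to 0.894 in plaque, and at 0.668 to 0.858 between groups (miRNAs are not independent replicates).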
